A study of Homo sapiens with 2 samples.

How the data were processed

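RNA sequencing of T47D breast cancer cells was examined in 2 samples, 1 stably transfected with the empty pCDH vector and 1 with pCDH-ZNF528-AS1. Per the labels' protocols, both grew in RPMI-1640 with 10% fetal bovine serum and 0.25 µg/ml puromycin, RNA was taken with Trizol, and libraries followed standard Illumina protocols. Whether the cells were clones or pools, and whether the libraries kept strand, is not given in the sources used here. Groups were taken from the labels of each sample, and each data column from its match to the sample's description.

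The deposited table lists 21638 genes. It holds raw read counts per gene for each library, per the file headers, and these deposited counts are the values used here. The submitters' processing notes name HISAT2, StringTie, HTSeq and DESeq and the build hg38, with no versions, roles or order. Beside the counts, the authors deposited CPM values, each count divided by 1 total per library, with a count of 0 written as 0.5 read. The totals implied by the deposited CPM exceed the listed counts by 4048 reads (0.0233%) with overexpression and 3575 (0.0205%) with vector. The authors' fold change column equals the ratio of the deposited CPM values, overexpression over vector, and their log2 column is the log2 of that ratio. The authors also deposited p-values and adjusted p-values for 1 library against 1, and the test behind them is not given in the sources used here. Those p-values are described as the authors' only and were set against an exact binomial p from the reads.

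All 21638 gene identifiers and their positions matched the GENCODE 29 annotation of GRCh38, from which transcripts, exons and overlaps between exons were taken. For 22 genes whose symbols had turned into dates, the symbol was restored from the identifier. Since no source states strand-specific counting, genes whose exons overlap another gene, and members of near-identical families, are given as uncertain. Genes first named in the closing section were not checked for this.

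Counts were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3), 1.01 for the overexpression library and 0.990 for the vector library. Genes with a mean of at least 1 scaled CPM over the 2 libraries, 14279 of them (12268 protein-coding), were compared. The log2 ratio was computed on scaled CPM plus a pseudocount of 0.5, which shrinks the ratios of low genes. The ratio printed for a gene is that of scaled CPM without a pseudocount, with an exact conditional binomial (Clopper-Pearson) 95% interval on the reads. Depth was nearly equal, at 17345432 reads with overexpression and 17434141 with vector, and 15772 and 15592 genes had at least 10 reads. Of the listed genes, 88 and 98 had 0 reads, which allows up to 3 reads.

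With 1 library per group no test across replicates exists, and no p-value was computed for a difference between the conditions; the exact binomial p served only to describe the authors' deposited p-values. A gene was counted as at least 2-fold higher or lower where its log2 ratio was at least 1 in size and its interval excluded a ratio of 1. For each of 35 gene lists, the median log2 ratio was ranked among 10000 random lists of the same size matched on 20 bins of expression. A list stood apart below the 2.5th or above the 97.5th percentile, which describes these libraries only, since genes of a pathway vary together. Lists with fewer than 3 compared members were not ranked. The groups, the lists, the size rule, the rule for named genes and the first set of alternative settings were fixed before the data were examined.

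Genes were named by that rule: ZNF528-AS1, ZNF528 and the 19q13 neighbours; ESR1, PGR, GATA3, FOXA1, GREB1 and TFF1; the 12 highest and 12 lowest log2 ratios among genes with a symbol, at least 100 reads in the higher library and an interval that excludes 1, without pseudogenes and clone names; and up to 4 members per list with the largest absolute log2 ratios. Some genes that the rule selects are not reported here. Further genes in the closing section were chosen after their values were seen.

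The steps were tested on simulated counts for 14307 genes drawn from the levels of these libraries. The size rule found 50 of 50 genes raised 3-fold and 45 of 50 lowered 3-fold, and 0 of 50 raised and 0 of 49 lowered by 1.5-fold. With counting noise only, and no spread between cultures simulated, it called 2 of 14108 unchanged genes. That number is therefore no rate of false calls between cultures. Of the intervals, 95.6% held the simulated ratio. Of 100 random lists of 30 genes 7 stood apart, and of lists raised by 0.3 in log2 100 of 100 did. The simulated genes varied independently with no spread between cultures, so these list numbers do not carry over to genes that vary together. Alternatives were DESeq2 1.42.0 median-ratio size factors, total-count scaling, pseudocounts of 0.1 and 2, no filter, a mean of at least 5 CPM, and protein-coding genes only. A 1.5-fold threshold and a correction for GC content and length were added after the data were seen. That correction removed the trends of the log2 ratio with GC content, exonic length and mean level together. Its effect is therefore not that of GC content and length alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.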

Results

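Total RNA was sequenced from T47D cells, an established human breast cancer line that expresses the estrogen receptor. The cells stably carried either the empty pCDH expression vector or pCDH holding ZNF528-AS1, a long RNA transcribed from the opposite strand next to the zinc finger gene ZNF528. There was 1 library per group, so no difference here has a replicate check, and each comparison describes these 2 libraries and not the conditions in general. The overexpression library held 17345432 reads counted in genes and the vector library 17434141, so that 1 read was worth 0.0571 and 0.0579 CPM, the count scaled to the library total. Mitochondrially encoded genes took 9.98% of the reads with overexpression and 9.63% with vector, and the 10 most abundant genes took 9.62% and 9.47%. Ratios are given as overexpression over vector, each with a 95% counting interval. The intervals and the detection floor of 3 reads (0.171 CPM with overexpression, 0.174 CPM with vector) cover counting error only.

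The label of the overexpression library was examined first, through the level of the introduced RNA. ZNF528-AS1 (ENSG00000269834) was 83.4-fold higher in the overexpression library (interval 70.0 to 100.02), with 10829 reads against 128 in the vector library, or 618 against 7.42 scaled CPM. It was the highest ratio among the 14279 genes compared. The gene lies on the minus strand of chromosome 19 from 52388842 to 52397766 (GRCh38), where the annotation gives 4 transcripts with 13 distinct exons. Reads of the introduced and of the chromosomal copy were counted together in the overexpression library.

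The neighbouring genes of 19q13, zinc finger genes and the phosphatase subunit gene PPP2R1A, went both ways. ZNF528, which starts 82 bp from ZNF528-AS1 on the opposite strand (chromosome 19, 52397849 to 52418412), was 1.40-fold higher (1.22 to 1.62), with 475 against 334 reads. That ratio stood at the 97.6th percentile of genes at a similar level, and the annotation gives no exon shared by the pair. Of the 31 neighbours compared, 16 were above and 15 below a ratio of 1, the counting interval lay above 1 for 6 and below 1 for 5, and their median log2 ratio of 0.02 was at the 50.9th percentile of random lists. ZNF83 was 1.51-fold higher (1.40 to 1.63) and ZNF665 1.92-fold higher (1.41 to 2.65), while ZNF614 stood at 0.770 of the vector level (0.632 to 0.937). ZNF577, at 1.78 (1.17 to 2.75), and ZNF649, at 0.625 (0.433 to 0.895), share exon sequence with each other, and the pseudogene ZNF137P, at 2.11 (1.33 to 3.40), has close relatives, so these ratios are uncertain. ZNF880, ZNF578 and ZNF677 had at most 11 reads in either library and were not compared.

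The question of which genes differed with ZNF528-AS1, named in the study's design, was addressed over the 14279 genes with a mean of at least 1 CPM. Most genes differed little on the scale with the pseudocount, where 93.9% were within 1.5-fold. The counting interval held 1 for 62.5% of the 14279 genes, which for genes with few reads does not show a small difference. The counting interval lay above 1 for 2475 of these genes and below 1 for 2884. Intervals narrow with more reads, so the counts of intervals given below for each list depend on depth as well as on the size of the differences. At least 2-fold higher were 75 genes (0.525%), and at least 2-fold lower were 66 (0.462%). At 1.5-fold the numbers were 486 higher and 337 lower. The 2-fold numbers were 149 higher and 115 lower with a pseudocount of 0.1 CPM, and 142 and 113 with no filter on low values. With a pseudocount of 2 CPM, 13 genes were higher and 28 lower by 2-fold, and with a mean of at least 5 CPM required, 24 were higher and 31 lower.

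**Figure D1:**
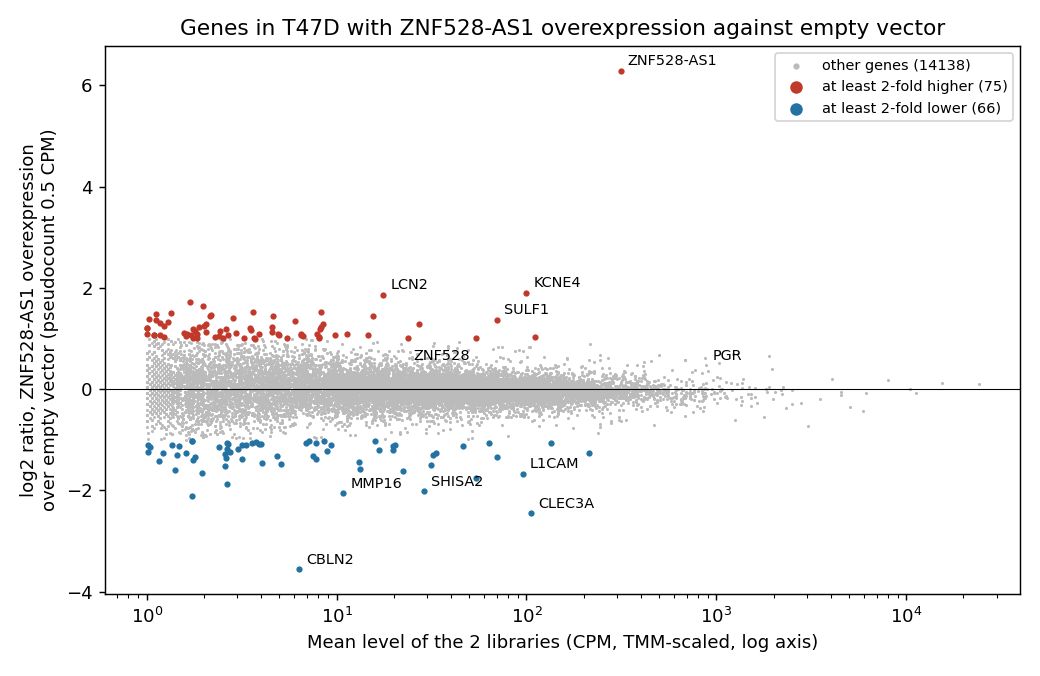
Log2 ratio of ZNF528-AS1 overexpression over empty vector (pseudocount 0.5 CPM) against the mean level of the 2 libraries in CPM on a log axis, 1 point per gene for 14279 genes. Red points mark the 75 genes at least 2-fold higher and blue points the 66 at least 2-fold lower; ZNF528-AS1 lies alone at a log2 ratio of 6.29.

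Behind ZNF528-AS1, the highest log2 ratios were those of KCNE4 and LCN2. KCNE4, a regulatory subunit of potassium channels, was 3.78-fold higher (3.48 to 4.11), at 158 against 41.7 CPM. LCN2, the secreted siderophore-binding lipocalin, was 3.83-fold higher (3.14 to 4.70), and the amino acid transporter SLC43A1 was 3.13-fold higher (2.38 to 4.16). EREG, which encodes the EGF receptor ligand epiregulin, was at 3.11 (2.15 to 4.58), and the inhibin subunit gene INHBE at 2.82 (2.32 to 3.45). SULF1, an extracellular heparan sulfate endosulfatase, was at 2.61 (2.39 to 2.86), with 1766 against 667 reads. Coagulation factor gene F7 was at 2.502, the homeobox gene HOXB9 at 2.60, the collagen gene COL27A1 at 2.60, and the calcium/calmodulin-dependent kinase gene CAMK2B at 2.40. TGFB1 was at 2.49 (1.92 to 3.25), but its exons overlap those of HNRNPUL1, so that its reads are uncertain.

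Among named genes with at least 100 reads in the higher library, the lowest log2 ratios were those of CBLN2, CLEC3A and MMP16. CBLN2, a synaptic organizer, had 10 reads with overexpression and 209 with vector, a ratio of 0.0471 (0.0223 to 0.0884). CLEC3A, a C-type lectin, was at 0.181 of the vector level (0.165 to 0.198), with 32.3 CPM against 178 CPM in the vector library. The membrane-bound metalloproteinase gene MMP16 was at 0.219 (0.166 to 0.286), and SHISA2 at 0.240 (0.204 to 0.280). L1CAM, a cell adhesion molecule of the immunoglobulin family, was at 0.311 (0.287 to 0.337), with 793 against 2509 reads. STS, the steroid sulfatase that frees steroids from their sulfates, was at 0.349 (0.304 to 0.400), and the aldehyde dehydrogenase gene ALDH3B2 at 0.292 (0.261 to 0.325). VTCN1, an inhibitory ligand of T cells, was at 0.318, COL5A1 at 0.317, NUDT8 at 0.319 and the kinesin gene KIF5C at 0.313. PDF, a mitochondrial deformylase gene whose exons overlap COG8, was at 0.352 and is uncertain for that reason.

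**Figure D2:**
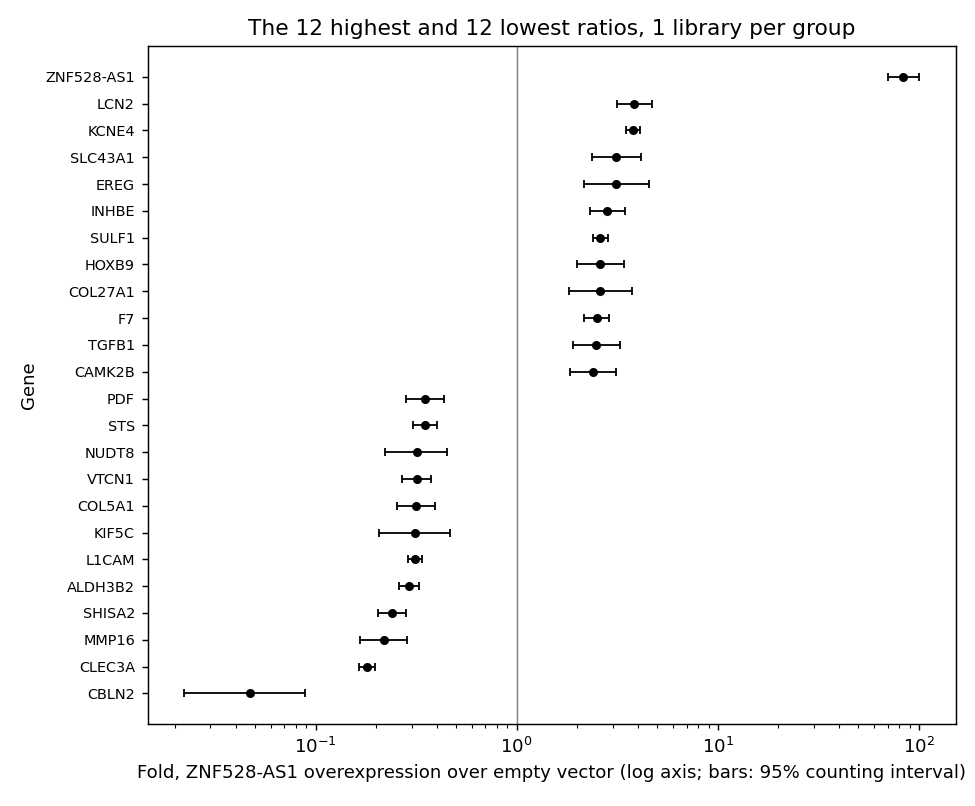
Ratio of ZNF528-AS1 overexpression over empty vector for the 12 genes with the highest and the 12 with the lowest log2 ratios among named genes with at least 100 reads in the higher library. Points are ratios on a log axis and bars are 95% counting intervals from 1 library per group; CBLN2, at 0.0471, is the lowest.

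The list of estrogen-induced genes was slightly higher, with members on both sides. ESR1, the estrogen receptor gene, was at 1.04 (0.980 to 1.096), a difference not detectable at this depth. PGR, the progesterone receptor gene, was 1.39-fold higher (1.36 to 1.42), although exons of PGR-AS1 overlap it, and GREB1, an estrogen-induced cofactor gene, was 1.28-fold higher (1.25 to 1.31). Of 38 estrogen-induced genes, 17 had a counting interval above 1 and 8 below 1. Their median log2 ratio was 0.10, above the central 95% of random lists (-0.09 to 0.04). WISP2 was at 3.45 (2.25 to 5.45), the EGF receptor ligand gene AREG at 1.78 (1.64 to 1.93), and IGFBP4 at 1.53 (1.495 to 1.57), while TGM2, whose exons overlap RPRD1B, was at 0.531 (0.297 to 0.924). With a mean of at least 5 CPM required, the list median was 0.06, still above random lists. TFF1 had 2 reads with overexpression and 8 with vector, a ratio of 0.246 whose interval ran from 0.0255 to 1.23.

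The luminal transcription factor genes GATA3 and FOXA1 were close to the vector level, while ELF3 and the keratin genes KRT8 and KRT18 were lower. GATA3 was at 0.911 (0.891 to 0.931) and FOXA1, whose exons overlap TTC6, at 0.955 (0.922 to 0.988). Of the 29 luminal identity genes, 7 had an interval above 1 and 14 below 1, and the median of -0.08 lay within the range of random lists (8.60th percentile), although after a correction for GC content and length, at -0.08, it lay below that range. KRT8 and KRT18, the paired keratins of simple epithelia, were at 0.608 (0.600 to 0.615) and 0.616 (0.597 to 0.636). Exons of this pair overlap on opposite strands, so some reads can be shared. ELF3, an epithelial transcription factor gene overlapped by ELF3-AS1, was at 0.550 (0.475 to 0.636), and BCAS1 at 0.582 (0.503 to 0.673).

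Genes of the unfolded protein response and its effector ATF4 were higher as a group. Of 38 members, 25 had a counting interval above 1 and 2 below 1. The median log2 ratio was 0.23, above the central 95% of random lists (-0.09 to 0.03). HSPA5, the main chaperone of the endoplasmic reticulum, was at 1.62 (1.58 to 1.65), with 26346 against 16073 reads. HERPUD1, a component of endoplasmic reticulum-associated degradation, was at 1.55 (1.43 to 1.68), and the glutathione-degrading enzyme gene CHAC1 at 1.56 (1.32 to 1.84). ASNS, asparagine synthetase, was at 5.47 (2.67 to 12.7), from 50 against 9 reads.

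Antigen presentation genes had the highest median of the lists with more than 6 members, and interferon-stimulated genes and NF-kB genes were also higher. Among 25 antigen presentation genes, 16 had an interval above 1 and 1 below, with a median log2 ratio of 0.35 (random lists -0.11 to 0.07). HLA-F, overlapped by HLA-F-AS1, was at 1.53 (1.36 to 1.73), although reads of the HLA genes can be split between near-identical copies. NLRC5, the transactivator of class I genes, was at 1.52 (1.36 to 1.70), and CIITA, the class II transactivator, whose exons overlap DEXI, at 1.58 (1.19 to 2.09). Of 46 interferon-stimulated genes, 21 had an interval above 1 and 6 below 1, with a median of 0.15. ISG20 was at 1.92 (1.54 to 2.39), XAF1 at 1.999 (1.32 to 3.09) and LGALS3BP at 1.71 (1.59 to 1.84), while IFI16 was at 0.465 (0.245 to 0.850). The 18 NF-kB and inflammatory genes had a median of 0.14, with 7 intervals above 1 and 1 below. LCN2 and BIRC3, an inhibitor of apoptosis at 1.64 (1.46 to 1.84), were higher in this list, while the chemokine gene CCL2 was at 0.466 (0.353 to 0.612).

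Cholesterol and fatty acid synthesis genes were lower. Of 26 cholesterol synthesis genes, 23 had a counting interval below 1 and 0 had one above 1, and the median log2 ratio was -0.29 (random lists -0.10 to 0.05). CYP51A1, the sterol demethylase, was at 0.587 (0.410 to 0.834). TM7SF2, overlapping VPS51, was at 0.651 (0.609 to 0.695), and mevalonate kinase gene MVK, overlapping MMAB, was at 0.671 (0.613 to 0.734). Of 27 fatty acid synthesis and lipid genes, 13 had an interval below 1 and 2 above 1, with a median of -0.18. The fatty acid uptake gene CD36 was at 0.602 (0.506 to 0.716), ELOVL6 at 0.701 (0.614 to 0.800) and ACLY, which makes cytosolic acetyl-CoA, at 0.740 (0.716 to 0.765), whereas DGAT2 was at 1.35 (1.13 to 1.62).

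Mitosis and histone genes were lower as lists, and the list of DNA replication genes lay within the range of random lists. Of 35 G2/M and mitosis genes, 24 had a counting interval below 1 and 0 had one above 1, and the median log2 ratio was -0.21 (random lists -0.09 to 0.04). CDC20, an activator of the anaphase-promoting complex, was at 0.680 (0.634 to 0.729), HMMR at 0.742 (0.678 to 0.813), the mitotic kinase gene PLK1 at 0.767 (0.722 to 0.815), and the proliferation marker MKI67 at 0.770 (0.736 to 0.804). The 39 G1/S and DNA replication genes had a median of -0.04, at the 20.6th percentile of random lists, with 3 intervals above 1 and 12 below. CCNE1, cyclin E, was at 0.647 (0.514 to 0.811), and thymidylate synthase gene TYMS, which overlaps ENOSF1, was at 1.55 (1.16 to 2.08). The 14 replication-dependent histone genes had a median of -0.30, with 9 intervals below 1 and 0 above. HIST2H2BE was at 0.682 (0.614 to 0.758) and HIST2H4A at 0.433 (0.291 to 0.635), although reads of such near-identical histone copies are uncertain.

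Ribosomal protein, YAP/TAZ and adhesion genes were lower as well. Of 74 cytosolic ribosomal protein genes, 51 had a counting interval below 1 and 2 above 1, with a median log2 ratio of -0.11 (random lists -0.08 to 0.00). After the correction for GC content and length, which also removes the trend with mean level, the median was -0.05, still below random lists. The part of each trend was not separated. RPS26 was at 0.739 (0.700 to 0.780) and RPS29, overlapping LRR1, at 0.729 (0.661 to 0.804). Both have processed pseudogenes that can share reads. The 18 YAP/TAZ target genes had a median of -0.28, with 11 intervals below 1 and 2 above. With no filter on low values it was -0.13, still below random lists. ANKRD1 was at 0.209 (0.0780 to 0.480), from 7 against 33 reads, TGFB2 at 0.736 (0.637 to 0.849) and AMOTL1 at 0.740 (0.626 to 0.875). Of 33 cell adhesion and tight junction genes, 20 had an interval below 1 and 3 above 1, with a median of -0.13. CLDN1, a tight junction claudin, was at 0.652 (0.639 to 0.664), with 17238 against 26062 reads, while CEACAM1 was at 1.65 (1.23 to 2.22). With no filter on low values, the adhesion list lay within the range of random lists at a median of -0.09.

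**Figure D3:**
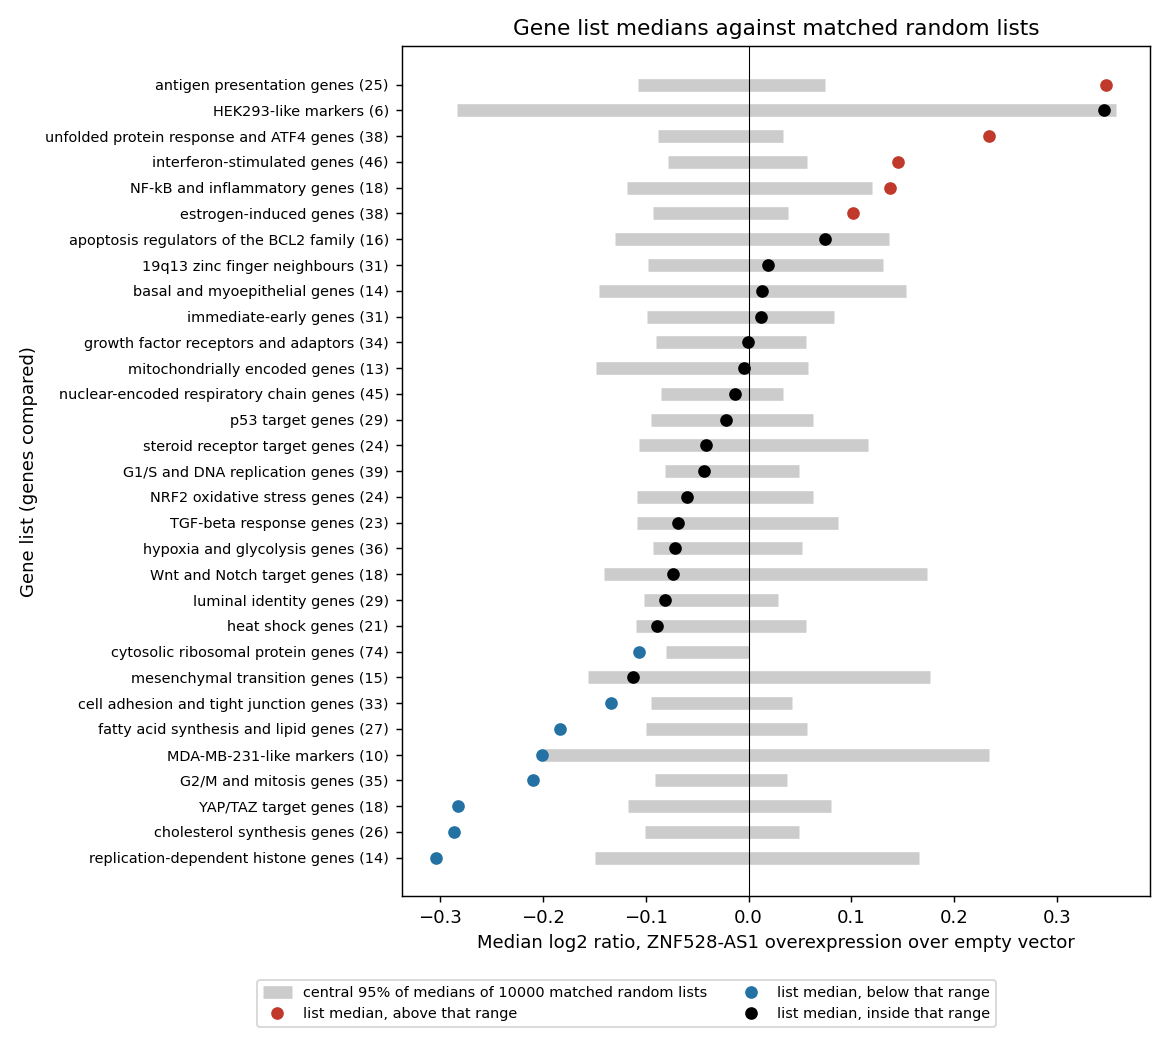
Median log2 ratio of ZNF528-AS1 overexpression over empty vector for each gene list with at least 5 compared members; the number of members is in parentheses. Grey bars span the central 95% of medians of 10000 random lists matched on expression, and red and blue points lie above and below them; antigen presentation genes stand at 0.35 and histone genes at -0.30.

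Of the 33 lists with enough members, 6 were above the central 95% of random lists, 8 below and 19 within it. About 1 list in 20 would lie outside by chance if its genes varied independently. Among the lists within that central range, the medians were 0.01 for immediate-early genes, -0.02 for p53 target genes, 0.07 for apoptosis regulators of the BCL2 family and -0.09 for heat shock genes. They were -0.07 for hypoxia and glycolysis genes, -0.01 for nuclear-encoded respiratory chain genes, 0.00 for mitochondrially encoded genes, and -0.06 for NRF2 oxidative stress genes. The medians were -0.07 for TGF-beta response genes, -0.07 for Wnt and Notch target genes, -0.04 for steroid receptor target genes, and 0.00 for growth factor receptor and adaptor genes linked to endocrine resistance. Only 3 metallothionein-list genes were compared (median -0.21). The p53 list was above random lists with no filter on low values (0.07), and the steroid receptor list below them with a mean of at least 5 CPM (-0.15).

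Single members of these lists differed by more. PLK2, a p53-induced kinase gene, was at 0.416 (0.396 to 0.437), with 2207 against 5226 reads, while the stress cytokine gene GDF15 was at 1.78 (1.66 to 1.91). PIP, an androgen-induced secreted protein gene, was at 0.393 (0.360 to 0.430). The ERK feedback genes DUSP4 and SPRY4 were at 1.64 (1.44 to 1.88) and 2.02 (1.37 to 3.01). FGFR1 was at 1.36 (1.28 to 1.45), with exons that overlap LETM2, and FGFR2 at 0.671 (0.588 to 0.765). BAMBI, a decoy receptor of TGF-beta signalling, was at 0.574 (0.504 to 0.652), and the Notch target HES1 at 0.647 (0.549 to 0.762). VEGFA was at 1.41 (1.33 to 1.49), and the glucose transporter gene SLC2A1 at 0.649 (0.548 to 0.767).

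The 14 basal and myoepithelial genes had a median log2 ratio of 0.01, and the 15 mesenchymal transition genes one of -0.11, both within the range of random lists. The mesenchymal median was 0.00 with no filter on low values, and -0.18, below random lists, after the correction for GC content and length. In the basal list 4 intervals lay above 1 and 2 below, with ACTA2, whose exons overlap FAS, at 1.46 (1.11 to 1.93), TAGLN, overlapping PCSK7, at 1.40 (1.17 to 1.67) and the integrin gene ITGB4 at 0.794 (0.758 to 0.831). In the mesenchymal list 3 intervals lay above 1 and 5 below, with THBS1, which overlaps FSIP1, at 0.592 (0.566 to 0.619). That list also holds COL5A1 and TGFB1, given above, which went opposite ways. Only 3 of 13 fibroblast markers passed the filter, and they went both ways: LUM at 0.675 (0.619 to 0.736), FBLN1 at 1.501 (1.09 to 2.08) and COL1A1 at 1.31 (1.20 to 1.42), with a median of 0.38 that lay above random lists. Of the 16 leukocyte markers 0 passed, and of the 12 endothelial markers 2 passed, FLT1 at 1.25 (0.856 to 1.82) and ESAM at 0.850 (0.625 to 1.16). The 10 markers of mesenchymal breast lines such as MDA-MB-231 had a median of -0.20, at the 2.39th percentile, and the 6 markers of HEK293-like lines a median of 0.35, at the 97.2nd. Both sat at the edge of the random range: the MDA-MB-231-like list lay inside it with a mean of at least 5 CPM (-0.07), and the HEK293-like list above it with a pseudocount of 0.1 (0.41).

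The authors' deposited table marks 489 genes as significant, 307 up and 182 down. Among them, the smallest absolute log2 fold change was 1.00067 and the largest adjusted p 0.049626 in the authors' deposited table. Of these, 138 up and 76 down had a mean below 1 CPM and were not compared here. Of the 169 up and 106 down that were compared, 75 and 66 met the size rule, and these were all the genes of that rule. Both rest on the same counts, and the pseudocount shrinks the ratios of the size rule. That overlap is therefore no independent check of either. The p-values of the authors' deposited table stood at a median of 0.943 times (95% range 0.793 to 0.986) an exact binomial p from the reads of the 2 libraries, over 10969 genes with at least 200 reads. Such a binomial p measures counting error between the 2 libraries and holds no spread between cultures. By those values alone 4106 genes (18.98%) had an adjusted p under 0.05 in the authors' deposited table, including KRT8, HSPA5 and MT-ND1, which it does not mark as significant and lists with differences below 2-fold.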

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

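The 1.5-fold threshold and the GC and length correction were chosen after the results were seen; the other settings were fixed before. On the scale with the pseudocount, the ZNF528-AS1 ratio was 78.2, and it was 65.9 with a pseudocount of 2, which shrinks any ratio. The numbers of genes at least 2-fold higher and lower, 75 and 66, became 149 and 115 with a pseudocount of 0.1, 13 and 28 with a pseudocount of 2, 142 and 113 with no filter, and 24 and 31 with a mean of at least 5 CPM, which leaves fewer genes. A 1.5-fold threshold gave 486 and 337. Median-ratio scaling (86 and 66), total-count scaling (87 and 64) and protein-coding genes only (58 and 54) stayed within 1.5 times the main numbers. The number of lists that stood apart was 13 to 15 in every setting (14 in the main one). The cell adhesion list was no longer apart with no filter (-0.09), and the MDA-MB-231-like list with no filter (-0.13), with a mean of at least 5 CPM (-0.07) or after the GC and length correction (-0.21); the cause was not tested. Lists newly apart were HEK293-like markers with a pseudocount of 0.1 (0.41) or a mean of at least 5 CPM (0.51), p53 targets with no filter (0.07), steroid receptor targets with a mean of at least 5 CPM (-0.15), and luminal (-0.08) and mesenchymal transition genes (-0.18, and 0.00 with no filter) after the correction. The fibroblast list had too few members to rank at a mean of at least 5 CPM. The lists apart in the main setting kept their sign in every setting; the p53 list, which was not, had -0.02 there. The median of estrogen-induced genes was 0.06 with a mean of at least 5 CPM, that of YAP/TAZ targets -0.13 with no filter, and that of ribosomal protein genes -0.05 after the correction. The scalings moved the median of all genes from -0.01 to at most 0.02. The setting with the authors' FPKM, RPKM or TPM was not run, since CPM is the normalized unit deposited beside the counts and differs from total-count scaling only by a slightly larger total and by zeros written as 0.5 read. No paired analysis was possible because each group has 1 library. Depth limits genes with few reads: the floor of 3 reads equals 0.171 and 0.174 CPM.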

Other observations

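The scan of GO terms and the genes named from it were chosen after the results were seen, as were the tests on culture state, on copy number of the MHC region and on list members outside the HLA genes. The terms given in the deposited table were ranked by the median of their genes' ranks within expression bins against random sets of equal size, over 1718 terms with 10 to 150 compared genes. Of these terms, 14 lay within the lowest 0.1 percent of random sets and 6 within the highest 0.1 percent. By chance 1.72 would lie on each side if genes varied independently. Genes of a term vary together and terms share genes, so these numbers do not measure an excess over chance. Keratinization was among the lower terms (31 genes, median log2 ratio -0.24), with 7 genes above and 24 below a ratio of 1 and 16 intervals below 1. Among the members with the largest differences were KRT19 at 0.683 (0.672 to 0.694), KRT7 at 0.690 (0.650 to 0.733) and KRT80 at 0.684 (0.654 to 0.716), beside KRT8 and KRT18. Exon overlaps and near-identical copies were not checked for genes first named in this section, such as KRT7, IFITM1 and IFITM3. Ribosomal large subunit biogenesis (28 genes, -0.15) and rRNA processing (141 genes, -0.07) were lower, as was positive regulation of cell-matrix adhesion (19 genes, -0.23). RHOB, a small GTPase gene within the term mitotic cytokinesis (48 genes, -0.12), was at 0.478 (0.450 to 0.508), with 1534 against 3161 reads.

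Among the higher terms were type I interferon signaling (43 genes, 0.25) and transport from the endoplasmic reticulum to the Golgi (138 genes, 0.05). In the interferon term, IFITM1 was at 1.89 (1.63 to 2.20), IFI6 at 1.53 (1.47 to 1.60) and IFITM3 at 1.49 (1.33 to 1.68). The transport term had 87 genes above and 51 below a ratio of 1, with 41 intervals above 1 and 20 below. Its largest differences were those of F7 and AREG, given above, and of COL7A1 at 2.16 (1.79 to 2.62). The coat protein gene SEC24D, with a smaller difference, was at 1.47 (1.32 to 1.64). Median log2 ratios by gene class, which were not tested, ran from -0.03 for 282 processed pseudogenes to 0.21 for 24 transcribed unitary pseudogenes, with 0.10 for 485 lincRNA genes, 0.10 for 537 antisense genes and -0.01 for 12268 protein-coding genes. MALAT1, an abundant nuclear noncoding RNA, was at 1.58 (1.55 to 1.60), with 40403 against 25272 reads, and NEAT1 at 1.11 (1.09 to 1.13).

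The higher unfolded protein response and ATF4 genes may reflect the overexpressed RNA or another state of the cultures, such as nutrient or density stress. GC content or gene length bias was argued against. After removal of those trends and of the trend with mean level, the list median was 0.27, at the 100th percentile of random lists. The culture state and the overexpressed RNA cannot be told apart for this list, or for any other list here, with 1 library per group.

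For the higher antigen presentation genes, a correction for GC content and length left the median at 0.38, which argues against that bias. Copy number of the MHC region could raise its genes together, but the 14 list members on chromosome 6 exceeded the 97 other genes from 29 to 34 Mb by 0.38 in median log2 ratio (bootstrap 95% interval over genes 0.23 to 0.51). The 16 members that are not HLA genes had a median of 0.14 (99.7th percentile), so the higher list did not rest on HLA genes alone. Those 16 cannot show whether reads moved between HLA copies. For class I genes, the summed reads of 9 genes and pseudogenes, at 1.46 (1.44 to 1.49), argued against such movement as the cause. The overexpressed RNA and the state of these cultures both stay open, untested, with 1 library per group.

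The lower G2/M and mitosis genes had a median of -0.18 after the GC and length correction, below all random lists, which argues against that bias. Histone genes, which are expressed in S phase, had a lower median (-0.30), but only 14 of 36 listed were compared and their reads are uncertain. The G1/S and DNA replication genes, at -0.04, lay within the range of random lists. A difference particular to G2 and mitosis is neither shown nor excluded by these lists. The overexpressed RNA, a difference in density or time since passage between the 2 cultures, and any other difference between the lines or libraries stay open, untested.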
